A study of Homo sapiens with 4 samples.

How the data were processed

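Replication timing was measured on 4 two-colour Agilent oligonucleotide arrays, 2 of RKO cells given a control siRNA against luciferase and 2 of RKO cells given a pool of siRNAs against POLQ. Per the labels' protocols, the siRNA was used at 50 nM with a medium change after 8 hours. Cells received 50 µM BrdU for 1 hour at 24 hours after transfection, were fixed and stained with propidium iodide, and 80000 cells were sorted into an early and a late S-phase fraction. BrdU-labelled DNA was immunoprecipitated from each fraction, amplified over the whole genome and labelled. Per the labels, the early fraction carried Cy3 and the late fraction Cy5 on all 4 arrays, with no dye swap. The labels call the arrays biological replicates and give each group the numbers 1 and 2.

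Each deposited file is one array's scanner output with 180880 spots, of which 174334 were not controls. Per the file headers, spots were quantified with Feature Extraction 11.5.1.1 and its CGH protocol, and probe positions are on hg19 (GRCh37). The submitters' processing notes name Feature Extraction 9.1, so the headers and the notes differ. The processed signals are intensities that, per the file headers, had been background-subtracted, spatially detrended and multiplied by 1 linear dye factor per channel, with no loess. The deposited spot and local background medians are raw intensities. The authors' LogRatio column is the log10 of Cy5 over Cy3, and it equalled the log10 ratio of the processed signals within 0.001 at 98.6% to 99.6% of spots per array. The deposited files also hold other values, flags of 0 or 1 for outlier spots, saturation and signal well above background. Per the file headers all 4 arrays lay on 1 slide with 1 scan time, so neither could act as a batch, and the planned slide block was not run.

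From these files the timing ratio was computed as log2(Cy3/Cy5) of the processed signals. Control spots and outlier spots were left out, spots of 1 probe were averaged, and probes missing on any array were dropped. Of 170334 probes, 168679 on chromosomes 1 to 22 and X were used. Probes were averaged over 100 kb bins with at least 3 probes, which gave 24162 bins. Each array was centred on its median and scaled to 1 common median absolute deviation, because the width of an early to late ratio depends on sorting and enrichment. No loess or quantile step was used, since most probes carry signal. The centring fixes the share of bins on either side of 0, so that share was not compared. POLQ and control arrays were compared per bin with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3) and Benjamini-Hochberg adjustment over all bins, with a threshold of 0.05. Every adjusted p of a bin, region or domain below comes from limma; those of the gene-density correlations are permutation p adjusted over the 4 arrays. Positive differences are higher Cy3 in the POLQ arrays. Passing bins of the same sign with at most 1 bin between them were merged into regions. Timing domains were runs of at least 5 bins of the same sign in the running median, over 5 bins, of the mean profile of all 4 arrays. Comparisons of single values over arrays used exact permutation tests, two-sided, for which 2 arrays against 2 allow no p under 0.333.

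The sum of the channels, log2(Cy3 + Cy5) of the processed signals, was also taken per spot, centred on each array's median and averaged over windows of 1 Mb (at least 10 spots) and 5 Mb (at least 50 spots). It is called total signal below. A block was a run of 5 Mb windows of at least 20 Mb in which the difference had the same sign and a size of at least 0.3. Protein-coding genes per chromosome were counted from a RefSeq gene table of GRCh38.p14 and divided by the length the probes span on hg19. No coordinate of that table was used.

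The groups, tests and alternatives above were fixed before the data were examined, except the total-signal measurements, the gene-density and probe-density comparisons, the flank counts and the restriction to bins of balanced total signal, which were chosen after the data were seen. The rule for named items took the 10 longest regions in each direction (ties by the larger mean difference) whose bins differed the same way in all 4 pairings of a POLQ with a control array. Regions were first ranked by number of called bins; the ranking was corrected to length, as the rule has it, after the values were seen, which brought in chromosome 19 from 19900001 to 21900000 in place of a region of chromosome 14. The rule also asked for genes in these regions and for gene lists. The files pair no probe with a gene and the gene table is on another build, so genes could not be placed, and the gene-list comparisons and the values at single genes are not reported here. Regions are named by hg19 coordinates instead. A timing array measures DNA and does not check how far POLQ was depleted. Alternatives were other scalings, dye and background corrections, filters, bin sizes, tests and thresholds, a replicate block, and each array left out in turn. The normexp alternative ran on the raw spot and background medians with an offset of 50, so it also left out the detrending and dye factors of the processed signals. The corrections for GC content need the hg19 sequence and were not run. The replicate numbers are not stated to mark a shared culture or day, and there are only 2 pairs, so they were not taken to pair the arrays.

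The bin test was tested on simulated data with 24162 bins and 200 changed ones. With spreads drawn from the fitted prior, 42 of 50 bins changed by 2 and 50 of 50 changed by 4 were recovered, against 0 of 50 changed by 1 and 1 of 50 changed by 0.5. Of the 100 calls, 7 were false. With each bin's own moderated spread, 50 of 50 bins changed by 2 and by 4, 13 of 50 changed by 1 and 1 of 50 changed by 0.5 were recovered, and 8 of 122 calls were false. With 5839 bins changed by 1.5, 94.9% were recovered and 238 of 5777 calls were false. That size was above the median called change in the data, 1.34, so this share does not hold for smaller changes. The domain test recovered 200 of 200 domains changed by 1 among 1063, with 11 false calls. No spot was saturated. The median spot lay 2.1 to 3 times above local background in Cy3 and 1.56 to 2.53 times in Cy5, and the number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9.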

Results

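Replication timing was profiled in RKO, a human colon carcinoma cell line, after transfection with a control siRNA or with siRNAs against POLQ. This gene encodes DNA polymerase theta, an enzyme known for joining broken DNA ends through short homologies. The series asks whether timing differs between the 2 conditions. Two-colour arrays compared newly made DNA from early and late S phase, with 2 arrays per group. Signal was well above background in both channels at 63.9% and 76.4% of spots on control arrays 1 and 2, and at 70.3% and 75.8% on POLQ arrays 1 and 2. Taken by channel, the groups did not overlap. In Cy3 the shares were 84.0% and 86.8% on control and 79.3% and 80.4% on POLQ arrays. In Cy5 they were 68.6% and 81.9% on control and 82.9% and 91.7% on POLQ arrays.

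All 4 arrays showed a genome divided into large domains that leaned to one dye or the other. Neighbouring 100 kb bins were alike, with a lag-1 autocorrelation of 0.854 ± 0.00964 (SD, n = 2) in control and 0.889 ± 0.00251 (SD, n = 2) in POLQ arrays. The control arrays' mean profile held 1052 domains with a median length of 1.8 Mb, and that of the POLQ arrays 1130 domains with a median length of 1.6 Mb. Across chromosomes the ratio ran from a strong lean to Cy3 on chromosome X, at 0.46 ± 0.11 (SD, n = 2) in control and 0.64 ± 0.12 (SD, n = 2) in POLQ arrays, to a lean to Cy5 on chromosomes 17, 19 and 22. Chromosome 17 stood at -0.50 ± 0.060 and -0.46 ± 0.13, and chromosome 22 at -0.48 ± 0.037 and -0.51 ± 0.094 (SD, n = 2 per group). Chromosome 19 stood at -0.23 ± 0.078 in control and at -0.59 ± 0.18 in POLQ arrays (SD, n = 2), the lowest mean in the latter. Gene-poor chromosomes 18, 8 and 4 leaned to Cy3 in control arrays, with means of 0.35, 0.28 and 0.36.

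This orientation was opposite to what the labelled dyes would give if gene-dense DNA replicates early, as it generally does in human cells. Over the 23 chromosomes, mean log2(Cy3/Cy5) fell as gene density rose on each array. Spearman's rho was -0.825 and -0.808 on control arrays 1 and 2 and -0.815 and -0.723 on POLQ arrays 1 and 2, with permutation p of 2e-05, 3e-05, 1e-05 and 0.00018 and adjusted values of 4e-05, 4e-05, 4e-05 and 0.00018 over the 4 arrays. The value 1e-05 is the smallest that 100000 permutations can give. Pearson's r was -0.693, -0.646, -0.814 and -0.720, with permutation p of 0.00012, 0.00066, 1e-05 and 0.00017 and adjusted values of 0.00023, 0.00066, 4e-05 and 0.00023. Without chromosomes 19 and 17, the farthest from the median gene density, r was -0.828, -0.793, -0.750 and -0.640. Bins with at least 10 probes had means between -0.47 and -0.31 on the 4 arrays, and bins with at most 5 probes had means between 0.43 and 0.54. The direction in time is therefore not settled. Changes are given below as toward Cy3 or toward Cy5. Toward Cy3 means earlier by the labels and later if early and late DNA were exchanged between the dyes, and toward Cy5 means the reverse. Counts and sizes do not depend on this choice.

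**Figure D1:**
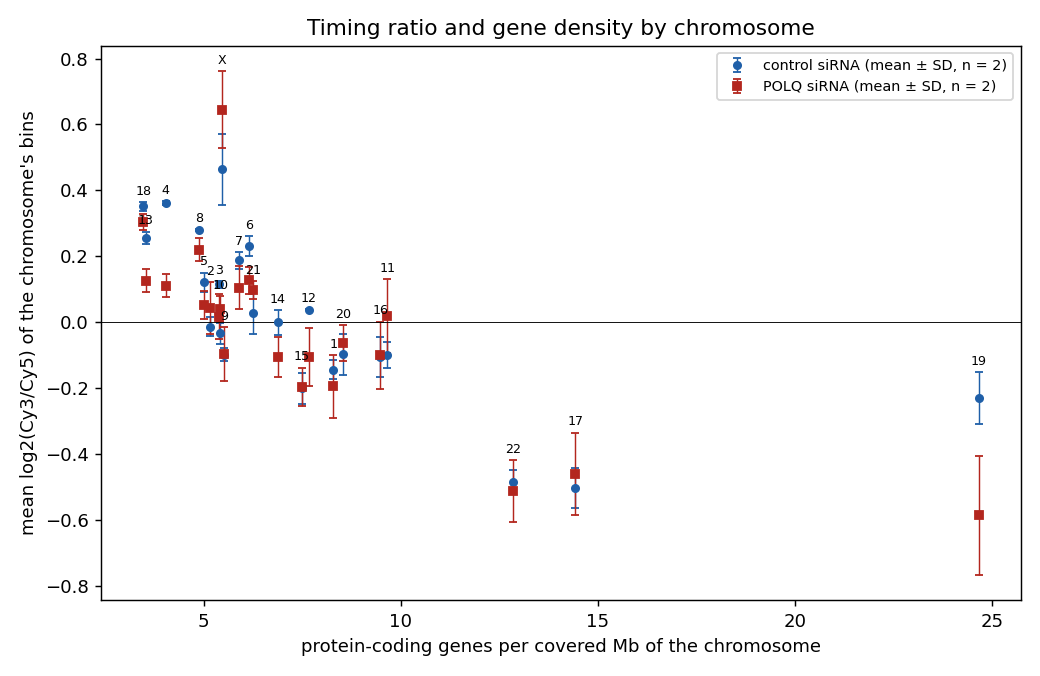
Mean log2(Cy3/Cy5) of each chromosome's 100 kb bins (y axis) against protein-coding genes per covered Mb (x axis), with points for the mean and bars for the SD of 2 arrays per group and chromosome names above. Gene-poor chromosomes 4 and 18 lie above 0 and gene-dense chromosomes 17, 19 and 22 below 0 in both groups.

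The POLQ arrays resembled each other and differed from the control arrays over large parts of the genome. Across bins, Pearson's r was 0.936 between the POLQ arrays and 0.872 between the control arrays, but only 0.601 to 0.671 between a POLQ and a control array (across bins, which are not independent). In a pair from different groups, 20.8% to 24.1% of bins lay on opposite sides of 0, against 10.4% between the control and 6.01% between the POLQ arrays. All 4 arrays lay on 1 slide, and the p-values below measure only the spread between these arrays.

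**Figure D2:**
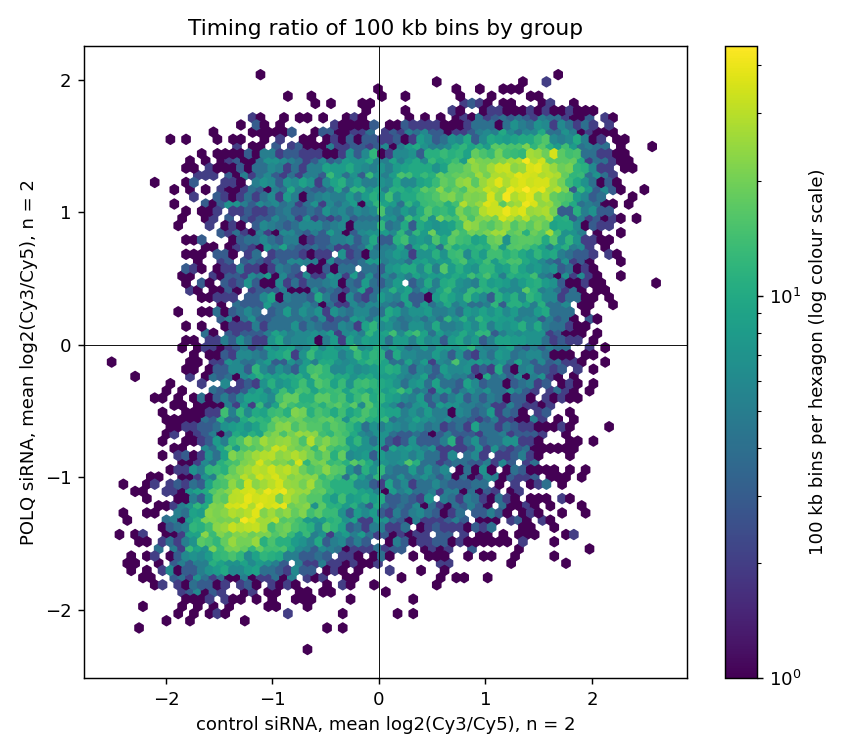
Mean log2(Cy3/Cy5) of 24162 bins of 100 kb in 2 POLQ siRNA arrays (y axis) against 2 control siRNA arrays (x axis), with colour for the number of bins per hexagon on a log scale. Most bins lie in clusters near the diagonal, and bins in the upper left and lower right quadrants changed sides, with r = 0.668 between the group means.

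Of the 24162 bins, 5839 (24.2%) changed at an adjusted p under 0.05 in limma. Of these, 2752 moved toward Cy3 and 3087 toward Cy5. The median size of a called change was 1.34 on the log2 scale and the smallest was 0.81, against a median standard error of 0.288. In 3786 of the called bins (64.8%) the group means lay on opposite sides of 0. The groups' arrays did not overlap in 60.7% of all bins, where chance gives 33.3%. Without POLQ array 1, 1706 bins moved toward Cy3 and 1630 toward Cy5, and without POLQ array 2 the counts were 1672 and 1681.

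The called bins formed 755 regions that moved toward Cy3 and 955 that moved toward Cy5, with a median length of 0.2 Mb. In all, 123 regions were 1 Mb or longer, 63 toward Cy3 and 60 toward Cy5. Of 744 regions with at least 3 called bins, 595 crossed from one side of 0 to the other. Among these, 297 had 1 flank that already lay on the new side in control arrays, 88 had both flanks there, 206 had neither, and 4 lay at a chromosome end. Of 1063 timing domains with a median length of 1.7 Mb, the domain means of 228 moved toward Cy3 and those of 259 toward Cy5 (limma, adjusted p under 0.05), which together held 932 Mb. Without POLQ array 1, 314 domains changed.

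The longest region that moved toward Cy3 lay on chromosome X from 9600001 to 13400000. Its 36 called bins went from -1.03 ± 0.10 in control to 1.14 ± 0.17 in POLQ arrays (SD, n = 2), a difference of 2.17, with adjusted p between 0.000505 and 0.0206. On chromosome 6, the region from 10600001 to 13300000 went from -1.11 ± 0.067 to 0.66 ± 0.059 (SD, n = 2). Chromosome 10 held 3 of the 10 longest regions. The region from 115900001 to 118200000 went from -0.75 to 1.02, that from 62200001 to 64600000 from -0.61 to 1.19, and that from 52700001 to 54700000 from -0.29 to 1.29. On chromosome 8, the region from 96500001 to 98500000 rose by 1.84, from -0.66 ± 0.35 to 1.18 ± 0.019 (SD, n = 2). The region from 239700001 to 241600000 on chromosome 1 rose by 1.88, and that from 227000001 to 229000000 on chromosome 2 by 1.88. Chromosome 9 from 117600001 to 119700000 and chromosome 4 from 86000001 to 87800000 rose by 1.62 and 1.47. With normexp background correction the differences of these 10 regions, over all their bins, were 0.45 to 0.77, against 1.41 to 2.17. The common spread to which arrays were scaled was 0.336 with that correction and 0.955 otherwise.

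The longest region that moved toward Cy5 lay on chromosome 19 from 51000001 to 54700000. Its 34 called bins went from 0.88 ± 0.044 in control to -0.91 ± 0.14 in POLQ arrays (SD, n = 2), with adjusted p between 0.000505 and 0.0307. The region of chromosome 19 from 36800001 to 38500000 went from 0.92 ± 0.068 to -1.15 ± 0.20 (SD, n = 2). Both flanks of these regions leaned to Cy5 in control arrays. The region of chromosome 19 from 19900001 to 21900000 went from 0.75 ± 0.17 to -0.82 ± 0.013 (SD, n = 2). The largest change among the 10 was on chromosome 6 from 26900001 to 29200000, from 1.33 ± 0.099 to -1.08 ± 0.0038 (SD, n = 2), a difference of -2.42. On chromosome 1, the region from 61100001 to 63400000 fell by 1.89 and that from 227800001 to 230000000 fell by 1.35. Under 50% of the bins of the latter were called without POLQ array 1, where the difference over all its bins was -1.13, against -1.31 with it. On chromosome 5, the region from 78500001 to 80700000 fell by 1.74 and that from 106700001 to 108800000 fell by 1.23. In the latter under 50% of bins were called without POLQ array 1 or 2, where the difference over all its bins was -1.14 or -1.07, against -1.16 with both. Chromosome 9 from 19500001 to 21300000 fell by 1.81. Chromosome 7 from 94300001 to 96100000 fell by 1.46 and ended near the middle, at -0.01 ± 0.12 (SD, n = 2), from 1.45 ± 0.066. With normexp the differences of these 10 regions, over all their bins, were -1.02 to -0.48, against -2.42 to -1.16, and that of chromosome 6 from 26900001 was -1.02.

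**Figure D3:**
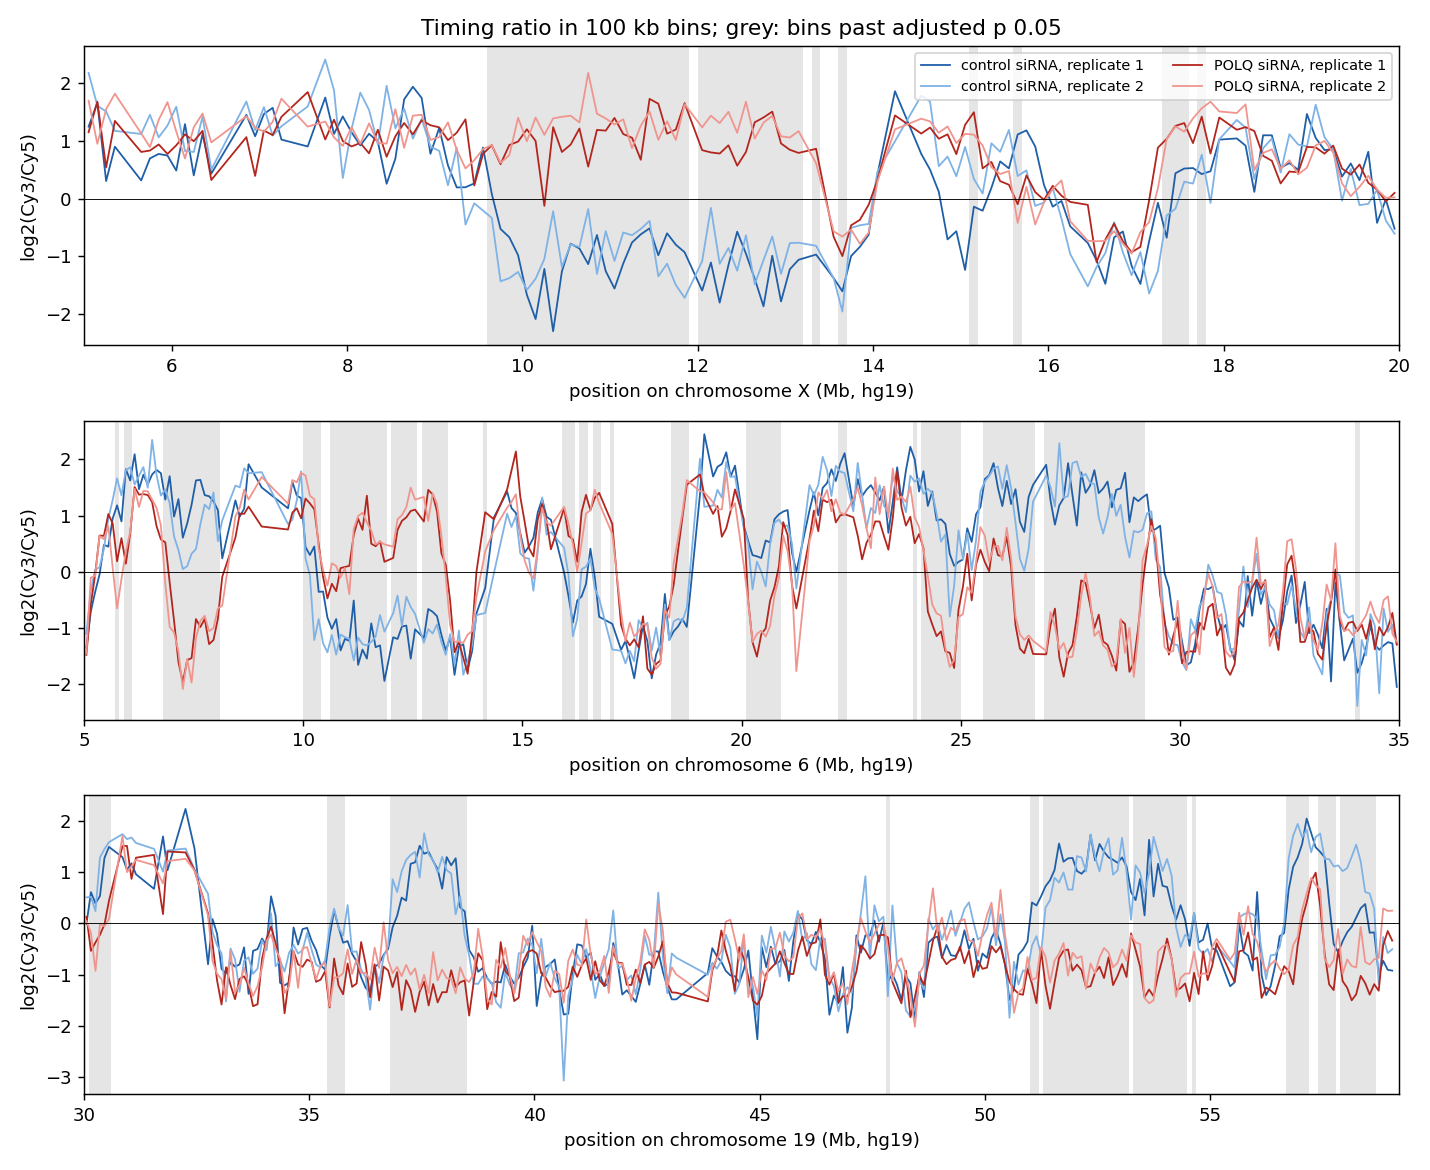
Log2(Cy3/Cy5) of 100 kb bins (y axis) along parts of chromosomes X, 6 and 19 (x axis, Mb on hg19), with blue lines for the 2 control and red lines for the 2 POLQ arrays and grey bands for bins past an adjusted p of 0.05. The arrays of each group run together, and the groups part over stretches of megabases, such as chromosome X from 9600001 to 13400000.

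Changed bins were found on every chromosome analysed, and their share differed between chromosomes. It was highest on chromosome 5, at 37.0% of bins, followed by chromosome 6 at 31.1% and chromosome 13 at 30.3%. It was lowest on the gene-dense chromosomes 22 and 17, at 10.4% and 12.5%, but was 20.3% on chromosome 19, the most gene-dense. Changes on chromosome 19 ran almost wholly one way, with 104 bins toward Cy5 and 2 toward Cy3, and its mean differed by -0.36. Chromosome 4 also moved toward Cy5, with 294 bins against 131 and a mean difference of -0.25. Chromosome X moved toward Cy3, with 181 bins against 58 and a mean difference of 0.18, and so did chromosome 11, with 141 against 58 and 0.12. These are the largest mean differences in each direction. The chromosome means of the POLQ and control arrays did not overlap on these and on others, 15 chromosomes in all, where chance gives 33.3%. With normexp background correction the mean differences were -0.056 for chromosome 19, -0.075 for chromosome 4, 0.11 for chromosome X and 0.048 for chromosome 11. These values are on a narrower scale, since the common spread was 0.336 with that correction and 0.955 otherwise. For chromosome 19 the fall from -0.36 to -0.056 was larger than this change of scale gives, so most of its shift depended on the processing. Without scaling to a common spread that of chromosome X was 0.35. For chromosome 19 the difference was -0.22 without POLQ array 1. For chromosome X it was 0.092 without POLQ array 2, 0.11 without control array 1 and 0.28 without control array 2. For chromosome 11 it was 0.037 without POLQ array 2 and 0.19 without POLQ array 1.

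Bins were split into 5 classes of equal size by the mean over all 4 arrays. A bin that changes sides has a mean near 0 by construction, so the shares of changed bins in the classes were not compared. In the class that leaned most to Cy3, 307 bins moved toward Cy5 and 37 toward Cy3, with a group mean of 1.41 ± 0.055 in control and 1.20 ± 0.11 in POLQ arrays (SD, n = 2). In the opposite class 129 moved toward Cy3 and 126 toward Cy5, with means of -1.24 ± 0.0096 and -1.24 ± 0.077 (SD, n = 2). The median difference of the Cy3 class minus that of the Cy5 class was -0.21 after scaling and 0.58 without scaling to a common spread. After scaling it was -0.13 without control array 1 or 2 and -0.34 without POLQ array 2.

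The width of the timing profile before scaling was larger in POLQ arrays. The median absolute deviation over bins was 0.903 and 0.760 in control arrays 1 and 2 and 1.08 and 1.12 in POLQ arrays 1 and 2, a difference of 0.27 between the group means, larger than the SDs of 0.102 and 0.0282. The arrays did not overlap, with an exact two-sided permutation p of 0.333, the smallest the design allows. With normexp background correction the difference between the groups was 0.14 in place of 0.27. The common spread was 0.336 with that correction and 0.955 otherwise, so the 2 differences are on unlike scales.

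Total signal, the sum of the dyes, also separated the groups, in blocks of many megabases. Over 582 windows of 5 Mb, the SD of the difference was 0.493 to 0.567 for a POLQ against a control array, 0.289 between the control arrays and 0.0659 between the POLQ arrays. Blocks of at least 20 Mb numbered 25 between the groups and covered 870 Mb. Total signal was higher in POLQ arrays by 0.80 on chromosome 8 from 65000001 to 145000000 and by 1.12 on chromosome 13 from 55000001 to 115000000. It was lower by -0.71 on chromosome 11 from 55000001 to 105000000 and by -0.50 on chromosome 5 from 110000001 to 160000000. The control arrays differed from each other in 9 such blocks with 370 Mb, the longest on chromosome 8 from 5000001 to 90000000, and the POLQ arrays in 0. Of the 20 named regions, 5 lay wholly in blocks that differed between the groups. These were chromosome 6 from 10600001, chromosome 8 from 96500001, chromosome 5 from 78500001, chromosome 7 from 94300001 and chromosome 19 from 36800001. Since the blocks covered 870 Mb of the 582 windows of 5 Mb, some overlap would arise for any set of regions. The other named regions were compared with these long blocks only, so they need not be free of a difference in total signal. Of 24162 bins, 13958 lay in 1 Mb windows where total signal differed by at least 0.3 between the groups. The changed share was 24.4% of these, and 25.3% of the 5370 bins where it differed by less than 0.15. The chromosomes with the largest mean shifts in timing ratio also differed in median total signal. POLQ arrays differed by -0.39 on chromosome 19, 0.35 on chromosome 4, 0.39 on chromosome X and -0.40 on chromosome 11. Chromosome 8, with a smaller mean shift of -0.059, differed by 0.67, but there the median of control array 1 minus control array 2 was -0.46.

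**Figure D4:**
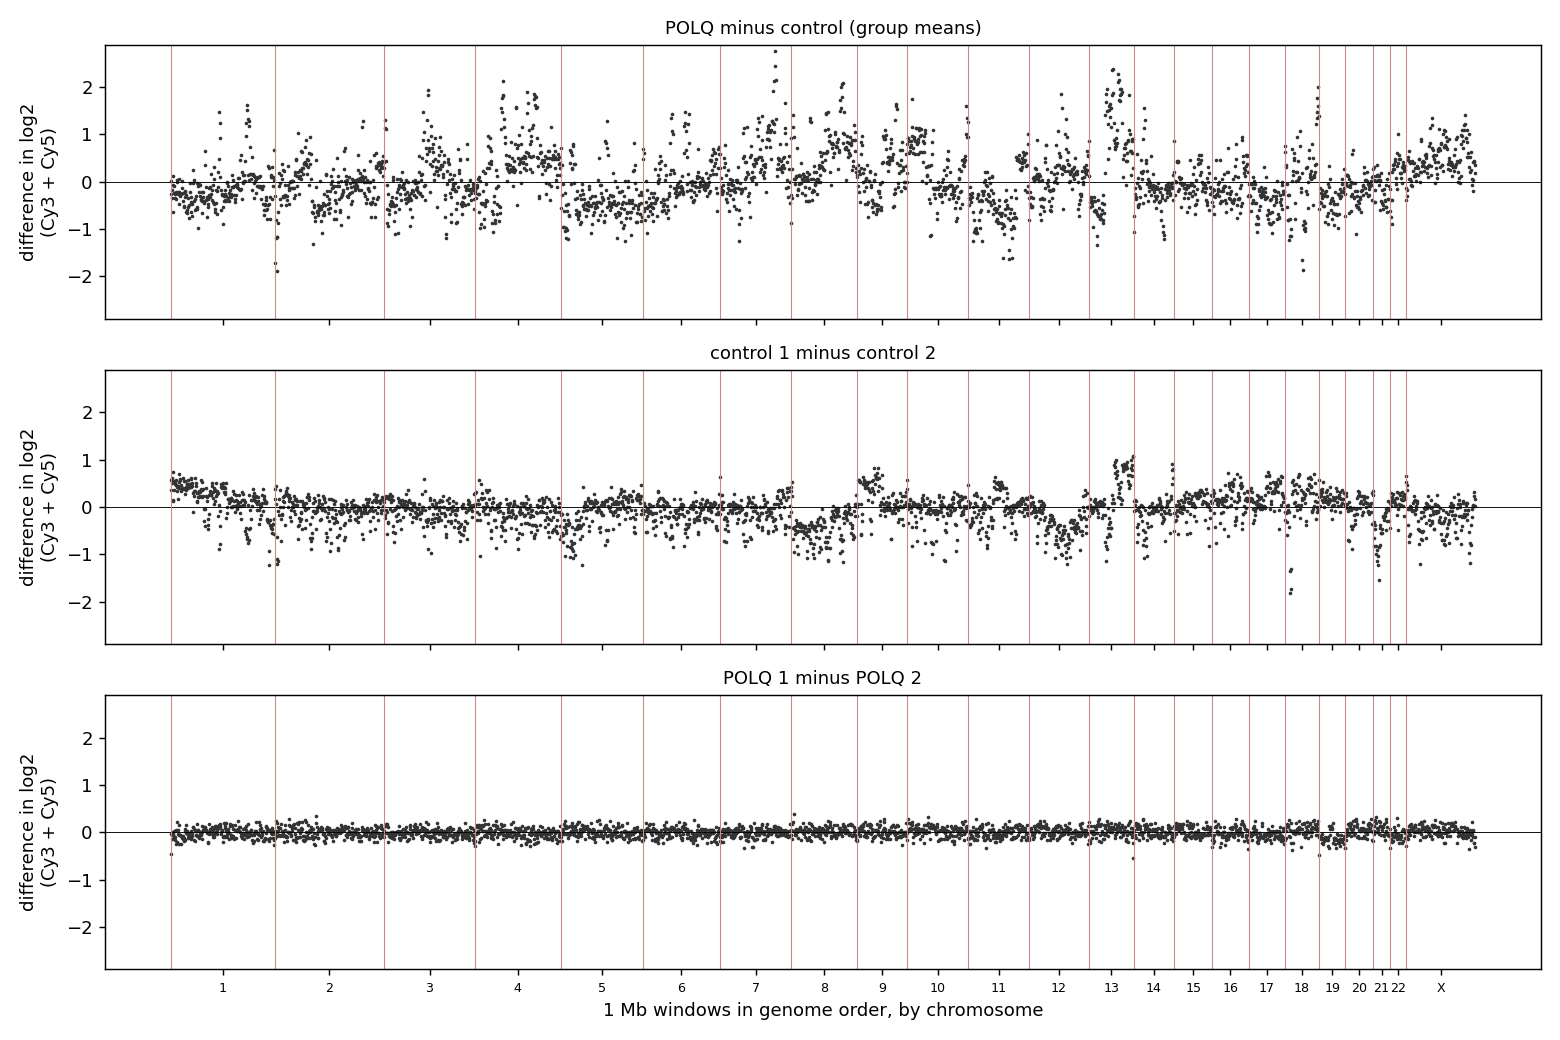
Difference in log2(Cy3 + Cy5) over 1 Mb windows in genome order (x axis, chromosomes marked by lines) between the group means, between the 2 control arrays and between the 2 POLQ arrays. The first panel and, less so, the second step up and down in blocks, while the third stays near 0, with SDs over 5 Mb windows of 0.507, 0.289 and 0.0659.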

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

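All tests below were chosen after the patterns were seen, and for all but the correlation of the separate channels and the comparison of balanced with unbalanced windows the tested values, or close ones, had been seen too. Total signal lies outside the timing ratio and drew attention because it differed between the groups beyond the level of the control pair. The difference of the group means had an SD of 0.507 over 5 Mb windows. The control arrays also differed from each other by at least 0.3 in 152 of 582 windows, where the POLQ arrays did so in 0.

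The first pattern is the set of blocks in total signal. The differences in total signal and timing ratio hardly ran together over the windows (r = -0.124), which argues against a source that moves both in proportion. This correlation alone cannot exclude a change of timing. The sum of the dyes can shift alike for moves toward either dye, and opposite moves can cancel within 5 Mb. A bias that follows base composition is argued against as the main source, since timing ratio and probe density, which stand in for it, explained 8.99% of the variance. The group differences of Cy3 and Cy5, measured apart, ran together over the windows (r = 0.705), though blocks were not called in each dye. DNA copy number that differed between the cells of the control and the POLQ arrays could give such a correlation. The control pair was not tested in this way, and GC content itself was not used here.

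The second pattern is the extent of the timing change. Changed bins were not more frequent where total signal differed, since their share in balanced windows was 1.04 times that in unbalanced ones. This cannot exclude a direct effect of copy number on the ratio. Balance was judged on group means of total signal centred on each array's median, which does not show equal copy number. The control arrays themselves differed by at least 0.3 in 152 of 582 windows of 5 Mb. Total signal differed more between the groups than within either, with the lowest between-group SD 1.71 times the highest replicate SD. One candidate explanation is that the control and POLQ arrays hold cells of different origin, such as another line or stock or a mislabelled set. Other differences that ran with the groups were not tested. The shares of spots well above background in each channel, for one, also did not overlap between the groups. An effect of POLQ siRNA cannot be told apart from a different origin or from such other differences, because every POLQ array also differed from every control array in total signal. The SDs of these pairs were 0.493 to 0.567 over 5 Mb windows. The arrays themselves do not tell which group, if either, was the unexpected one.

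The third pattern is the orientation of the dyes. An exchange of early and late DNA between the dyes or the fractions on all 4 arrays stays open, and the highest rank correlation with gene density, -0.723, is the pattern itself and no separate test of it. A dye bias fixed by sequence is argued against as the whole of the ratio, since replicates correlated better than arrays of different groups by 0.201 at the least. Such a bias as a part of the ratio stays open, because probe sequences were not used here.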

How the results depend on the processing

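Of the 5839 called bins, 3198 (at an adjusted p of 0.01) to 5839 (replicate block) were called again with the same sign in the settings that tested all of them on the same bins with no array left out. The sign of the difference, called or not, turned in 14 of them under normexp and in 0 under the others. Settings that change only the test, the threshold or the block keep the difference itself, so no sign could turn there. The bin counts of 2752 and 3087 were 1624 and 1574 at an adjusted p of 0.01, and 3466 and 3152 with 50 kb bins, of which 35436 were tested. Restricted to 5370 bins of balanced total signal, a setting chosen after the data were seen, they were 650 and 737, from fewer bins tested. With 200 kb bins 314 of 798 domains changed. Leaving out 1 array gave 1672 to 3292 bins toward Cy3, 1630 to 3808 toward Cy5 and 314 to 576 domains; the lone array of a group was then assumed to vary like the other group. The gap between the outer timing classes was 0.58 without scaling, -0.0032 with quantile normalization, -0.11 with normexp, -0.083 with 200 kb bins and -0.34 to -0.13 with 1 array left out, so its sign depends on the scaling. The mean difference of chromosome 4 was -0.19 without scaling, -0.20 with quantile normalization, -0.075 with normexp and -0.28 to -0.22 with 1 array left out. That of chromosome X was 0.35 without scaling, and that of chromosome 19 was -0.056 with normexp. The difference in profile width was 0.14 with normexp. The cause of these changes was not tested. Normexp values are on a narrower scale, with the common spread of 0.336 given below. The fall for chromosome 19 was larger than that scale gives. With the replicate number as a block, 3482 bins moved toward Cy3, 4073 toward Cy5, and 527 domains changed. Deviations of same-numbered arrays correlated at 0.167. The 20 named regions kept their direction in each of 120 comparisons under 6 other scalings, corrections and bin sizes. These settings used the same arrays on which the regions were chosen for long runs of called bins. Their direction could therefore hardly turn, and keeping it is no independent support. With an array left out or the replicate block the direction was largely fixed by how the regions were chosen or by the fit. Their differences were 1.77 to 3.43 times smaller with normexp, and the common spread was 0.336 in place of 0.955; this setting also changed the input to raw medians and added an offset of 50. In 3 comparisons, all without a POLQ array, under 50% of the bins were called: chromosome 1 from 227800001 and chromosome 5 from 106700001. Gene-list and GC alternatives and the slide block were not run. The number of arrays limits the precision; signal over background was lowest in Cy5 of control array 1, at 1.56 times.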
